A study of Mus musculus with 16 samples.

How the data were processed

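Bulk RNA sequencing of sorted mouse cells was measured in 16 libraries, 4 in each of 4 groups named by the labels: CX3CR1-positive microglia of control brain, CX3CR1-positive microglia of the ischemic hemisphere, CD11c-eYFP-positive cells of the ischemic hemisphere and CD11c-eYFP-positive cells of the spleen. According to the labels, tissue was dissociated with enzymes, passed over Percoll and sorted by the fluorescence of the reporters without antibody staining, and stranded libraries of polyadenylated RNA were made. The counts of reads per gene are values as deposited by the authors, who checked reads with FastQC 0.11.5 and aligned them with STAR 2.5.3a to the mouse genome GRCm38. The program that counted reads, its strand setting, the gene annotation release, the time between ischemia and sorting, and the disease state of the spleen donors are not given in the sources used here. All values in the file were whole numbers, every column belonged to a sample, and raw reads were not analysed here.

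The file held 50600 genes, of which 50376 had a name in GENCODE release M21 or a name table, 224 had none, and 29525 had a count in at least 1 library. Gene coordinates are those of GENCODE release M21 on GRCm38. Depth was 31.57 to 48.25 (units of 1e6 counts) with a mean of 39.379 ± 4.286 (SD, n = 16), so that 1 CPM before scaling stands for 31.57 to 48.25 counts. Counts per library unit are printed as CPM scaled by TMM factors, and log2 CPM were made with a prior count of 2. Fold changes are those of the edgeR fit at its default settings, without further shrinkage.

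Comparisons were fixed before the data were examined, as were the gene lists, the rule for naming genes and most alternatives. CD11c cells of the ischemic brain were compared with ischemic microglia, ischemic with control microglia, and CD11c cells of the brain with those of the spleen. The test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) under R 4.3.3, with TMM scaling and genes kept by filterByExpr, on all 16 libraries in a single model with a mean for each group. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels name no block or covariate that could be fitted. Standard errors are those of the log2 fold change, and standard deviations are between the 4 libraries of a group.

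Genes specific to CD11c cells of the brain had to pass with a log2 fold change of at least 1 against each of the other 3 groups. Genes specific to microglia had to pass in the same way in all 4 contrasts of a microglia group with a CD11c group. The counts were set beside 20 simulated count tables without group differences, which cannot gauge the overlap of contrasts that do differ. The sharing of genes between the ischemia comparison in microglia and the comparison of brain with spleen was tested with Fisher's exact test, two-sided. The 2 comparisons share no library, but both come from the single model, and the test treats genes as independent of each other.

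The 34 gene lists, written from general knowledge of cell types and pathways, covered microglia (homeostatic, reactive), dendritic cells (conventional, type 1, type 2, mature, plasmacytoid), antigen presentation (MHC class I and class II), monocytes, border macrophages, neutrophils, T, natural killer, B, plasma and erythroid cells, neurons, astrocytes, oligodendrocytes, endothelial cells, the cell cycle, interferon response, inflammation, chemokines, chemokine receptors, immediate early and heat shock genes, glycolysis, cholesterol synthesis, lipid handling, complement, growth factors, costimulation and innate sensors. Of their genes 97.9% were measured. Lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 34 lists. They were tested again with a correlation estimated from the residuals of all 16 libraries, the same for a list in each comparison. They were also tested with fry, which tests a list without reference to other genes. Where no test is named, a list passed or did not pass by camera with the preset correlation. Members were counted by their edgeR call over all genes and by a call adjusted over the list alone.

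Genes were named by rule. In each comparison, among genes with an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and no overlap between the 2 groups of 4 libraries, and leaving out predicted genes, mitochondrial genes and antigen receptor segments, the 8 largest differences in each direction and the 4 most abundant in each direction with a log2 fold change of at least 2 (1 between the microglia groups) were eligible. For each list, up to 3 called members with the largest changes in the direction of most members and 1 in the other were eligible, and further members could be named with values. Itgax and Cx3cr1 are given in every group, and genes named as specific to a population are from its 8 most abundant. Some eligible genes are not reported here. Il1r2, Dab2, Fosl2, Cytip and Cst7 were named after values were seen. Genes with 0 counts in a group are given as a lower bound against a floor of 3 counts over the group, and genes with 1 to 3 counts as a ratio with an exact interval. Gapdh, Pgk1, Pgam1 and Idi1 have near-identical copies in the genome, as have Hspa1a and Hspa1b and the haemoglobin genes, and their counts are uncertain.

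Alternatives were RLE, upper-quartile and library-total scaling, no filter, a filter of 1 CPM in 4 libraries, glmTreat against a log2 fold change of 1, DESeq2 1.42.0, limma-voom with sample quality weights, only the 2 groups compared, leaving out each library in turn, leaving out, between brain and spleen, the 2 CD11c libraries whose titles share the number 11, other minimum fold changes, and lists without members of other lists. After the data were seen, the CD11c libraries of the brain titled in either style were also used alone, and immunoglobulin genes were left out. The edgeR fit and test were run on simulated data made from these counts with 200 genes changed, 50 at each of 4 sizes. This recovered 70, 82 and 72% of genes changed by 2-fold in the 3 comparisons and 94% or more at 4-fold. Of the calls 2.5, 4.29 and 5.19% were false, which rests on 4, 7 and 8 genes. Changed genes had at least 1 CPM, and libraries of a group were drawn from the same mean. The real comparisons called far more than 200 genes. The CD11c libraries of the brain also split by title style, so these shares may not hold there. A search for single libraries set apart in their group of 4 used the gap to the nearest library over the range, with a limit that chance passes in about 1 of 20 groups. Haemoglobin shares were at first rounded to 4 decimals, which set a library apart in 3 groups at almost 0, and with 4 significant digits this remained in 1 of them.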

Results

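RNA was sequenced in bulk from 16 libraries of sorted cells of male mice aged 13 to 14 weeks, 4 libraries in each of 4 groups. Microglia, the resident macrophages of the brain, were sorted as CX3CR1-positive cells from control brain and from the ischemic hemisphere of mice that carry an inducible Cre recombinase under the Cx3cr1 promoter and a tdTomato reporter. CD11c-eYFP-positive cells were sorted from the ischemic hemisphere and from the spleen of mice in which the Itgax promoter drives a yellow fluorescent protein. Itgax encodes CD11c, an integrin subunit carried by dendritic cells and by some macrophages, and the submitters call the CD11c cells of the brain infiltrating. Each library held 31.57 to 48.25 (units of 1e6) counted reads, with a mean of 39.38 ± 4.29 (SD, n = 16), over 16941 to 22169 genes with a count, and 16345 genes were tested.

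The first principal component of log2 CPM (counts per 1e6) held 67.7% of the variance and the second 16.4%. Pearson correlations of log2 CPM across genes were 0.987 to 0.992 among control microglia, 0.985 to 0.992 among ischemic microglia, 0.952 to 0.986 among CD11c cells of the brain and 0.980 to 0.990 among spleen CD11c cells. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of 10.2 or more for every pair. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries. The CD11c libraries of the brain spread most on the third component, where replicates 1 and 2 had scores of 18.7 and 22.9 and replicates 3 and 4 had −49.7 and −65.3.

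**Figure D1:**
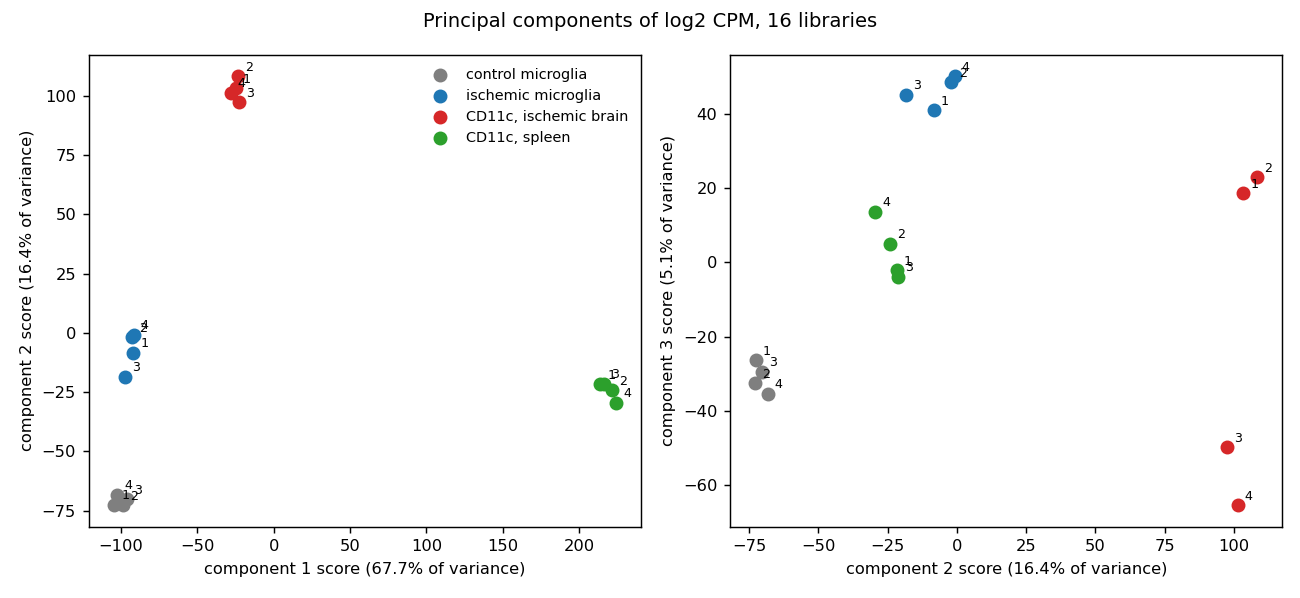
Scores of the 16 libraries on principal components 1 and 2 (left) and 2 and 3 (right) of log2 CPM, in arbitrary units, with 1 point per library, colour for the group and the replicate number beside each point. The 4 groups lie apart on components 1 and 2, which hold 67.7% and 16.4% of the variance, and CD11c brain replicates 3 and 4 lie at −49.7 and −65.3 on component 3.

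Of the genes behind the sorting reporters, Itgax followed the sorted populations. Cx3cr1 was highest in microglia but differed more between brain and spleen than between microglia and CD11c cells of the brain. Itgax (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657, protein-coding) stood at 30.4 ± 3.93 CPM in control microglia, 77.2 ± 28.0 in ischemic microglia, 756 ± 208 in CD11c cells of the brain and 573 ± 169 in spleen CD11c cells (SD, n = 4 each). Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, protein-coding), the fractalkine receptor of microglia and of some monocytes, stood at 3128 ± 211, 1912 ± 188, 1312 ± 85.1 and 29.1 ± 6.78 CPM in the same order. Itgax rose in ischemic microglia by 1.34 ± 0.29 log2 units (SE; edgeR adjusted p = 0.00231) and did not pass the test between brain and spleen CD11c cells (log2 0.40 ± 0.29; adjusted p = 0.234; 0.08 with brain replicates 1 and 2 and 0.64 with 3 and 4, neither called). Cx3cr1 fell in ischemic microglia by 0.71 ± 0.14 log2 units (adjusted p = 0.00123) and was lower again in CD11c cells of the brain than in ischemic microglia (log2 −0.54 ± 0.14; adjusted p = 0.00666). Transcripts of the male Y chromosome were present in every library, with Ddx3y at 109 to 189 CPM before scaling, and the female transcript Xist reached at most 0.457 CPM before scaling.

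**Figure D2:**
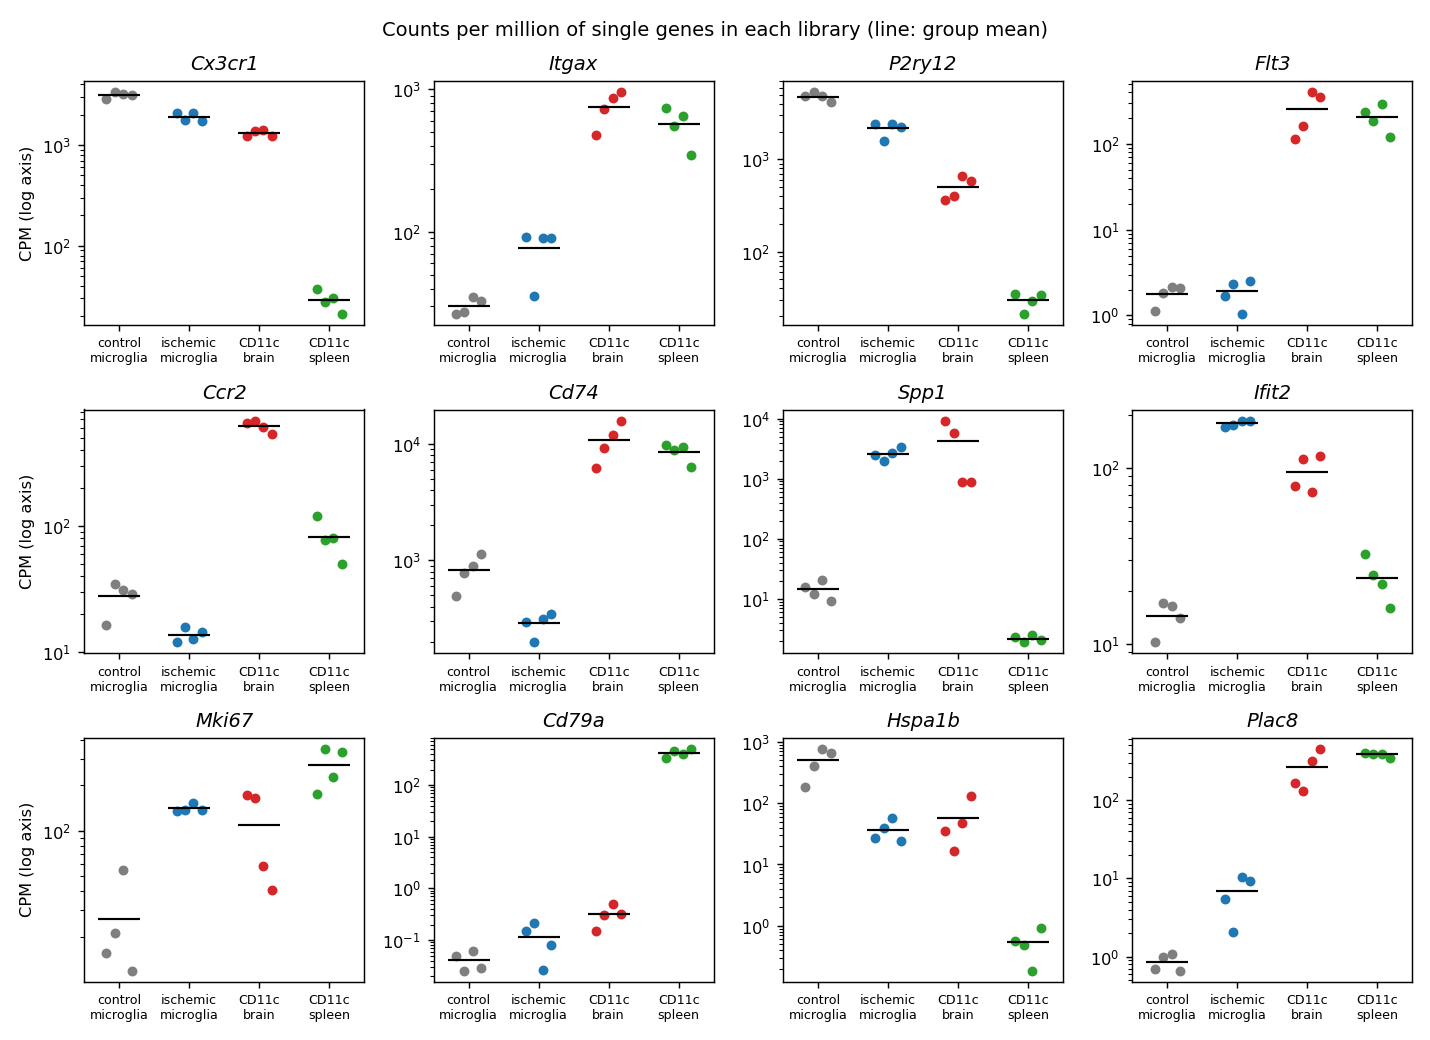
CPM (log axis) of 12 genes in each of the 16 libraries, with 1 point per library, 4 libraries per group and a line at the group mean. Itgax lies at group means of 756 and 573 CPM in the CD11c groups against 77.2 and 30.4 CPM in microglia, and P2ry12 at 4793 and 2166 CPM in microglia against 506 and 29.8 CPM in the CD11c groups.

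CD11c cells and microglia of the ischemic hemisphere were compared to find genes specific to each population, the question stated for the series. Genes of MHC class II antigen presentation, by which peptides are shown to CD4 T cells, were the most abundant of those higher in CD11c cells. Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain that escorts class II molecules, stood at 10780 ± 4081 CPM in CD11c cells against 290.4 ± 65.1 CPM in ischemic microglia (SD, n = 4 each; log2 5.21 ± 0.33, SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.9e-09). H2-Aa and H2-Eb1, which encode peptide-binding chains, were higher by 5.95 and 6.11 log2 units. P2ry12 (chromosome 3, 59216272 to 59262871), the ADP receptor of microglial processes, stood at 506 ± 146 CPM in CD11c cells against 2166 ± 406 CPM in microglia (log2 −2.10 ± 0.21; adjusted p = 9.65e-07).

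The genes named next had large differences in favour of CD11c cells and means of 0.0905 to 2.56 CPM in microglia. Htr7 (chromosome 19, 35958734 to 36057507), a serotonin receptor gene, had the largest log2 difference among genes at 20 CPM or more with 8.64 ± 0.51 (37.7 ± 5.39 against 0.0905 CPM; adjusted p = 2.57e-09; 9.23 without ischemic microglia replicate 4). Kit and Flt3, growth factor receptors of haematopoietic progenitors that dendritic cells keep, were higher by 8.01 and 7.08 log2 units, and Dpp4, a surface peptidase, by 7.80. Cdh1 (E-cadherin) was higher by 8.02 and Itgb7, an integrin subunit of leukocyte homing, by 6.79. On the other side, Esr1, the oestrogen receptor, was lower by −3.60 log2 units (3.14 ± 0.24 against 38.2 ± 6.57 CPM), C4b, a complement component, by −2.22, and Sparc, a secreted matrix protein of microglia, by −2.07. Lyve1 and Cd163, receptors typical of macrophages along brain borders and vessels, were lower in CD11c cells by −3.71 and −2.83.

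Dendritic cell lists other than the plasmacytoid list were higher in CD11c cells. Counts adjusted over the list alone were the same as those over all genes unless a second pair is given. Of the 14 measured members of the conventional dendritic cell list, 12 were higher and the other 2 were not called (median log2 4.57, camera adjusted p = 2.4e-11, adjusted p = 0.132 with an estimated correlation). In the type 1 list 11 of 16 were higher and 3 lower (median 2.80, adjusted p = 6.3e-05, adjusted p = 0.37 with an estimated correlation). Its members included Ly75, an endocytic receptor (5.84), and Itgae, an integrin subunit (4.65). In the type 2 list 10 of 15 were higher and 1 lower, or 12 and 1 adjusted over the list alone (median 1.76, adjusted p = 5.63e-05, adjusted p = 0.286 with an estimated correlation). Cd7 was higher by 7.80 and Tnip3 by 4.53, with Sirpa lower (−0.81). The mature dendritic cell list had 13 of 20 higher and 2 lower, or 13 and 3 adjusted over the list alone (median 1.74, adjusted p = 2.92e-06, adjusted p = 0.355 with an estimated correlation). Members included Ccr7, the receptor for lymph node homing (5.38; 204 ± 56.1 against 4.88 CPM), Traf1 (5.17) and the chemokine Ccl22 (3.74), with Cd83 lower (−1.05). The plasmacytoid dendritic cell list went both ways, with 7 of 14 higher and 5 lower (adjusted p = 0.19), with Spib, a transcription factor, at 6.44.

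Lists of MHC class II, migration and monocyte genes were higher in CD11c cells as well. Where no second pair of counts is given, the counts adjusted over the list alone equalled those over all genes. In the MHC class II list 12 of 15 were higher and 2 lower (median 1.94, camera adjusted p = 2.92e-06, adjusted p = 0.37 with an estimated correlation), while the class I list did not pass (3 of 17 higher and 2 lower; median 0.01; adjusted p = 0.565). The chemokine receptor and migration list had 13 of 19 higher and 3 lower, or 14 and 3 adjusted over the list alone (median 2.84, adjusted p = 2.92e-06, adjusted p = 0.0273 with an estimated correlation). Ccr2, the receptor that draws monocytes out of bone marrow, stood at 622 ± 65.6 CPM against 13.8 ± 1.73 (log2 5.49; adjusted p = 6.45e-10). In the monocyte list 11 of 16 were higher and the others not called (median 4.74, adjusted p = 2.92e-06, adjusted p = 0.132 with an estimated correlation). Members included Plac8 at 5.28 and Thbs1 at 4.71. The T cell list had 10 of 16 higher and 1 lower, or 11 and 1 adjusted over the list alone (median 2.47, adjusted p = 0.038, adjusted p = 0.567 with an estimated correlation). Most of its members were near the floor in CD11c cells of the brain, such as Cd3e at 0.056 to 1.28 CPM, while Il7r stood at 45.5 to 109 CPM. With brain replicates 1 and 2 alone 5 of 16 were higher, and with 3 and 4 alone 10. Cholesterol synthesis genes had 7 of 18 higher and 2 lower (median 0.23, adjusted p = 0.0233, adjusted p = 0.567 with an estimated correlation).

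Lists of microglial identity, inflammation and complement were lower in CD11c cells than in microglia. The counts over all genes also held adjusted over the list alone unless a second pair is given. All 20 members of the homeostatic microglia list were lower (median log2 −1.53, camera adjusted p = 3.31e-12, adjusted p = 0.0273 with an estimated correlation). The CD11c libraries still held Csf1r at 3950 ± 469 CPM, against 11230 ± 128 in microglia. The inflammatory list had 10 of 19 lower and 1 higher, or 11 and 2 adjusted over the list alone (median −0.69, adjusted p = 0.02, adjusted p = 0.567 with an estimated correlation). The early inflammatory cytokines Tnf and Il1a were lower by −1.83 and −1.85 log2 units. Il1b was higher by 0.89, but was not called by limma-voom or with only CD11c brain replicates 1 and 2 (0.36). Complement genes had 7 of 13 lower and 1 higher (median −0.68, adjusted p = 0.0334, adjusted p = 0.567 with an estimated correlation). Members included C1qa at −1.16 and Cfp (properdin) at 4.15. Immediate early and heat shock genes had 8 of 19 lower and the others not called (median −0.43, adjusted p = 0.0141, adjusted p = 0.573 with an estimated correlation). Egr2 was lower by −1.45. Neuron genes had 9 of 13 lower and the others not called (median −1.71, adjusted p = 0.000453, adjusted p = 0.37 with an estimated correlation). Camk2a stood at 3.75 ± 2.13 against 19.3 ± 5.30 CPM. The reactive microglia list did not pass the test (7 of 22 higher and 5 lower; median −0.24, mean 0.37; adjusted p = 0.923), nor did the border macrophage list (2 of 12 higher and 6 lower, or 2 and 8 adjusted over the list alone; median −0.91; adjusted p = 0.0841). By fry the border macrophage list was lower in CD11c cells (adjusted p = 0.00646).

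**Figure D3:**
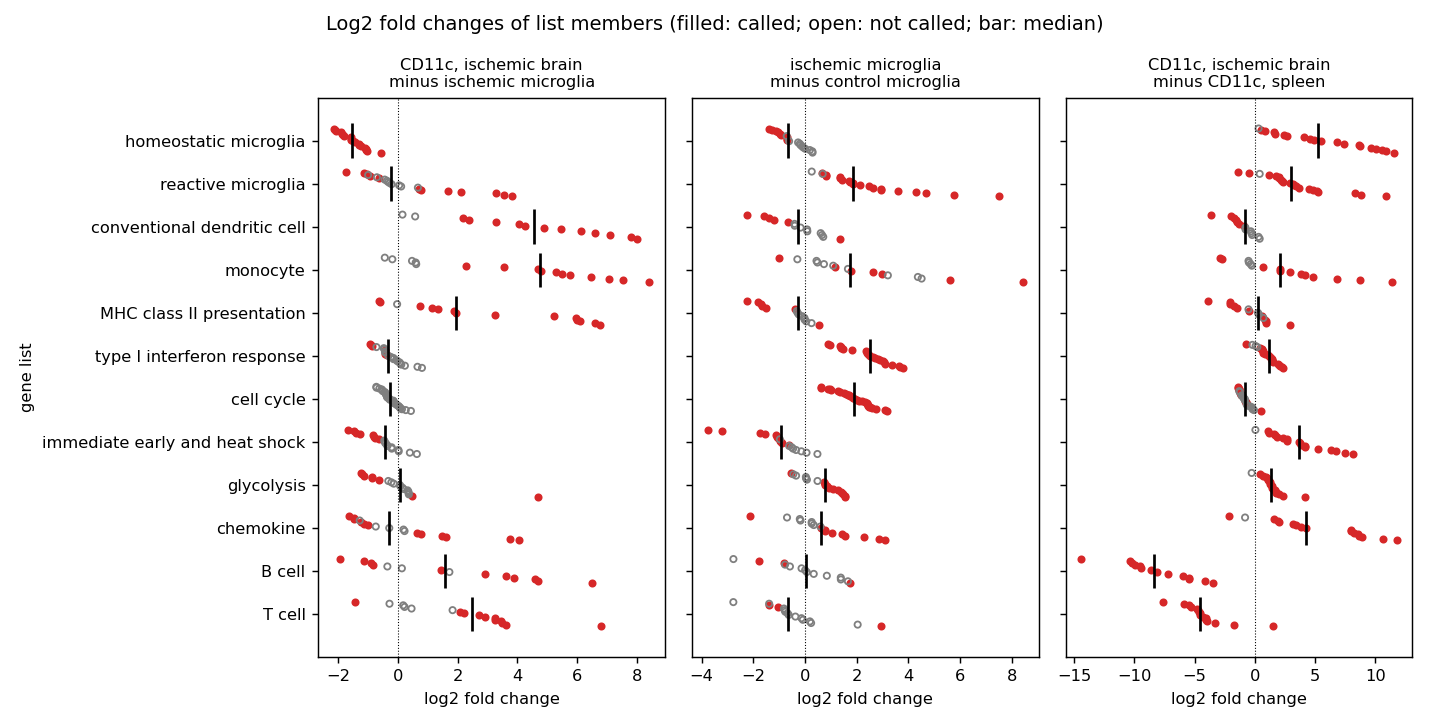
Log2 fold changes of the members of 12 gene lists in the 3 comparisons, with 1 point per gene (filled red: adjusted p under 0.05; open grey: not called) and a black bar at the list median. In the left panel all 20 homeostatic microglia genes lie below 0 with a median of −1.53 and the conventional dendritic cell list has a median of 4.57, in the middle panel the interferon list has a median of 2.51, and in the right panel the B cell list has a median of −8.35.

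Of the 16345 genes, 3213 were higher and 3130 lower in CD11c cells than in microglia (38.8%; 1687 and 1270 of them by 2-fold or more), and 50.7% of the calls were higher. With library totals in place of composition scaling the split was 3964 and 2388 (62.4% higher), and the median over all genes moved from 0 to 0.097. In 2442 genes all 4 CD11c libraries lay above all 4 microglia libraries and in 2698 below, where chance would give 2.86% of genes in both directions together. For called genes given with a value in any comparison, all 4 libraries of 1 group lay above all 4 of the other, except for 3 of 4 libraries in Il1b, Cst3 and the neutrophil gene S100a9 here and in Serinc3 between brain and spleen. The scores of called lists lay apart in the same way in 13 of 14 lists here, 16 of 16 between microglia groups and 20 of 21 between CD11c groups. Medians and means differed in sign for chemokines (−0.28 and 0.15), growth factor and repair (−0.77 and 0.09), costimulation (−0.01 and 1.72) and innate sensor genes (−0.40 and 0.35). None of these lists passed by camera, and fry called only costimulation among them, as higher (adjusted p = 2.18e-07). The mouse lines differed with the sorted population, so line and population cannot be parted in this comparison.

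Ischemic microglia were compared with control microglia. Secreted phosphoprotein 1 (Spp1, osteopontin; chromosome 5, 104435118 to 104441050) rose from 14.3 ± 4.91 to 2620 ± 562 CPM (SD, n = 4 each; log2 7.52 ± 0.75, SE; edgeR adjusted p = 4.56e-06), and Fn1 (chromosome 1, 71585520 to 71653200), the matrix protein fibronectin, from 4.70 to 1628 ± 647 CPM (log2 8.43 ± 0.77; adjusted p = 1.98e-06). Saa3, an acute phase protein, rose by 8.44 ± 1.10 (41.9 ± 52.0 CPM against 0.120), and by 7.03 without ischemic microglia replicate 2. Cspg4, Trem1, Cd5l and Gpnmb rose by 7.43, 7.23, 7.09 and 5.76 log2 units. Trem1 amplifies inflammatory signals, Cd5l is a macrophage survival protein and Gpnmb a glycoprotein of lipid-laden macrophages. Among the most abundant transcripts the lysosomal proteases Ctsd and Ctsb rose by 1.26 and 1.70, to 15920 ± 2466 and 13160 ± 1448 CPM, Apoe by 1.44 and the lysosomal protein Grn by 1.62.

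Type I interferon response genes rose as a group, 23 of 23 over all genes and adjusted over the list alone (median log2 2.51, camera adjusted p = 1.09e-20, adjusted p = 0.18 with an estimated correlation). Ifit2, an inhibitor of viral translation, rose from 14.4 ± 3.13 to 179 CPM and Rsad2 (viperin) by 3.68 log2 units. In the reactive microglia list 20 of 22 rose, or 21 adjusted over the list alone, and the others were not called (median 1.86, adjusted p = 9.26e-15, adjusted p = 0.18 with an estimated correlation). Ch25h rose by 4.70, Clec7a by 2.64 and Igf1 by 1.84. All 29 cell cycle genes rose, also adjusted over the list alone (median 1.91, adjusted p = 5.74e-13, adjusted p = 0.418 with an estimated correlation). Mki67 rose from 26.0 ± 19.9 to 141 ± 8.67 CPM (log2 2.43, or 3.09 without control microglia replicate 3) and Ccnb2 (cyclin B2) by 3.08 log2 units. The cell cycle score was 3.720 in control microglia replicate 3, 2.647 to 2.865 in the other control libraries and 4.602 to 4.896 in ischemic microglia. MHC class I presentation had 11 of 17 higher, or 12 adjusted over the list alone, and the others not called (median 0.66, adjusted p = 3.75e-07, adjusted p = 0.18 with an estimated correlation), with its transactivator Nlrc5 at 2.13 and H2-D1 at 1.35. Class II genes went the other way without passing as a list (6 of 15 lower and 1 higher; median −0.29; adjusted p = 0.0904): Ciita, their transactivator, fell by 2.24 log2 units, H2-Aa by 1.70 and Cd74 by 1.51.

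Inflammatory, lipid, glycolysis and growth factor lists rose in ischemic microglia. Counts adjusted over the list alone were the same as those over all genes unless a second pair is given. The inflammatory list had 13 of 19 higher and the others not called, or 13 higher and 1 lower adjusted over the list alone (median 0.95, camera adjusted p = 1.91e-05, adjusted p = 0.266 with an estimated correlation). Il1rn, an interleukin 1 antagonist, rose by 3.65, Ptgs2 (cyclooxygenase) by 2.35 and Tnf by 1.46. The chemokine list had 9 of 17 higher and 1 lower (median 0.63, adjusted p = 0.011, adjusted p = 0.434 with an estimated correlation). Cxcl10, an interferon-induced attractant of T cells, rose by 3.10 and Ccl17 fell by 2.13. Complement had 9 of 13 higher, or 10 adjusted over the list alone, and the others not called (median 0.49, adjusted p = 0.000906, adjusted p = 0.418 with an estimated correlation). C3 rose by 3.19 and C4b by 2.25. Lipid handling had 9 of 16 higher and 1 lower, or 9 and 2 adjusted over the list alone (median 0.69, adjusted p = 0.00954, adjusted p = 0.434 with an estimated correlation), with the lipid droplet protein Plin2 at 2.97. Glycolysis had 12 of 19 higher and 1 lower (median 0.77, adjusted p = 0.000906, adjusted p = 0.434 with an estimated correlation), with the lactate exporter Slc16a3 at 1.54 and the glucose transporter Slc2a1 at 1.08. Growth factor and repair genes had 8 of 18 higher and the others not called (median 0.69, adjusted p = 0.00329, adjusted p = 0.418 with an estimated correlation). Csf1, a growth factor of macrophages, rose by 2.11. Costimulation and checkpoint genes had 8 of 15 higher and 1 lower, or 9 and 1 adjusted over the list alone (median 1.00, adjusted p = 0.000457, adjusted p = 0.18 with an estimated correlation), with the checkpoint genes Cd274 at 2.36 and Pdcd1 at 2.68 and Vsir at −0.77. The mature dendritic cell list had 13 of 20 higher and 2 lower (median 0.82, adjusted p = 0.000801, adjusted p = 0.434 with an estimated correlation). The monocyte list had 6 of 16 higher and 1 lower, or 7 and 1 adjusted over the list alone (median 1.72, or 1.41 with genes without counts at their bound, adjusted p = 0.00128, adjusted p = 0.366 with an estimated correlation).

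The homeostatic, immediate early and type 2 dendritic cell lists were lower in ischemic microglia with the preset correlation. Lists without a second count had the same counts over all genes and adjusted over the list alone. In the homeostatic list 10 of 20 fell and the others were not called (median −0.65, camera adjusted p = 0.00128, adjusted p = 0.385 with an estimated correlation). P2ry12 fell by 1.15 log2 units, P2ry13 by 1.30 and Slc2a5, a fructose transporter, by 1.39, while Csf1r (log2 −0.21) did not pass the test. In the immediate early and heat shock list 11 of 19 fell, or 14 adjusted over the list alone, and the others were not called (median −0.94, adjusted p = 0.000197, adjusted p = 0.434 with an estimated correlation). Hspa1b (chromosome 17, 34956436 to 34959238), a heat shock chaperone, stood at 504 ± 262 CPM in control and 36.9 ± 14.8 CPM in ischemic microglia (log2 −3.77 ± 0.60; adjusted p = 0.000256), Hspa1a fell by 3.20 and Jun by 1.75. The type 2 dendritic cell list had 5 of 15 lower and the others not called (median −0.71, adjusted p = 0.0105, adjusted p = 0.434 with an estimated correlation), with the lectins Cd209a and Mgl2 at −3.56 and −2.39. Cst3 (cystatin C), the most abundant transcript of control microglia, fell from 15930 ± 1691 to 6996 ± 1878 CPM. Innate sensors went both ways (8 of 22 higher and 5 lower, or 9 and 5 adjusted over the list alone; median 0.30; adjusted p = 0.0603), with Tlr2 at 2.27 and Tlr5 at −2.47.

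Of the 16345 genes, 2889 were higher and 2945 lower in ischemic than in control microglia (35.7%; 1231 and 894 of them by 2-fold or more), and 49.5% of the calls were higher. With library totals alone the split was 2140 and 4242 (33.5% higher), and the median over all genes moved from −0.051 to −0.199. All 4 ischemic libraries lay above all 4 control libraries in 3256 genes and below them in 3816.

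CD11c-eYFP-positive cells of the ischemic brain were compared with those of the spleen. Genes known from microglia and from macrophages in injured tissue were higher in the brain cells. Fcrls, a microglial receptor gene, stood at 1541 ± 520 CPM against 0.516 in spleen (SD, n = 4 each; log2 11.55; edgeR adjusted p = 4.28e-13), and Thbs1 (thrombospondin 1; chromosome 2, 118111876 to 118127133) at 2773 ± 2348 against 1.02 CPM (log2 11.41 ± 0.77, SE; adjusted p = 5.19e-09). Spp1 was higher by 10.91 ± 0.87, and by 10.12 without CD11c brain replicate 1. Adamts1, a matrix protease, had 12733 counts in the brain libraries and 2 in spleen, a ratio of 8353 (95% counting interval 2312 to 68980). The cathepsin genes Ctsd and Ctss were higher by 4.35 and 2.88, at 7447 ± 1962 and 6304 ± 379 CPM in the brain cells, and Apoe by 3.14.

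B lineage and erythroid genes were among the largest differences on the other side. Cr2 (chromosome 1, 195136811 to 195176716), complement receptor 2 of B cells and follicular dendritic cells, had 2 counts in the brain libraries and 386 ± 98.0 CPM in spleen, a ratio of 26190 (interval 7249 to 216200). Jchain, the joining chain of secreted antibodies, stood at 5287 ± 1565 CPM in spleen and 3.88 ± 5.33 in brain (log2 −10.40; −12.03 without CD11c brain replicate 3). Car1, an erythroid carbonic anhydrase, and Prg2, an eosinophil granule protein, had 0 counts in the brain libraries and were at least 2305-fold and 1065-fold higher in spleen, taking 3 counts over the group as the floor. Car1 varied widely in spleen (50.7 ± 53.0 CPM), its fitted log2 moved from −13.97 to −13.02 without spleen replicate 4, and limma-voom did not call it (adjusted p = 0.0869). Such intervals and floors cover counting error only. Slc40a1 (ferroportin, the iron exporter) and the adhesion molecule Vcam1, both known from red pulp macrophages, were lower in the brain cells by −5.27 and −4.80, at 1499 ± 225 and 1388 CPM in spleen.

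For the lists of blood cells the counts over all genes and those adjusted over the list alone were the same. All 14 B cell list members were lower in the brain cells (median −8.35, camera adjusted p = 9.28e-11, adjusted p = 0.00581 with an estimated correlation). Members included Cd79a at −10.34. The plasma cell list had 6 of 8 lower and the others not called (median −2.83, adjusted p = 0.0052, adjusted p = 0.239 with an estimated correlation). The T cell list had 15 of 16 lower and 1 higher (median −4.52, adjusted p = 0.000106, adjusted p = 0.295 with an estimated correlation). The natural killer list had 11 of 15 lower and 1 higher (median −4.03, adjusted p = 0.00143, adjusted p = 0.378 with an estimated correlation). The neutrophil list had 12 of 14 lower and 1 higher (median −6.14, adjusted p = 0.000528, adjusted p = 0.295 with an estimated correlation). The erythroid list had 7 of 7 lower (median −12.15, or −9.87 without spleen replicate 1, adjusted p = 0.00222, adjusted p = 0.342 with an estimated correlation), with a list score of 7.75 in spleen replicate 1 and 3.18 to 5.75 in the other 3. Immunoglobulin genes took 7.71 to 21.7% of the counts of the spleen libraries (mean 13.0 ± 6.09%, SD, n = 4) and at most 0.0653% elsewhere. Spleen CD11c libraries held Cd4 at 139 ± 58.5 CPM and Prf1, a pore-forming protein of killer cells, at 11.1 ± 1.24 CPM. Prf1 had 0 counts in the brain libraries and was at least 506-fold higher in spleen.

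Lists of microglia, inflammation and tissue repair were higher in the brain cells. Apart from the inflammatory list, the counts over all genes and those adjusted over the list alone were the same. The homeostatic microglia list had 19 of 20 higher and the other not called (median 5.20, camera adjusted p = 3.99e-14, adjusted p = 0.0158 with an estimated correlation). Sparc was higher by 10.89 and Trem2 by 10.51. The reactive list had 19 of 22 higher and 2 lower (median 3.04, adjusted p = 3.3e-08, adjusted p = 0.239 with an estimated correlation). The monocyte list had 10 of 16 higher and 2 lower (median 2.11, adjusted p = 0.0265, adjusted p = 0.364 with an estimated correlation, adjusted p = 0.0998 without members of other lists). The border macrophage list had 9 of 12 higher and 2 lower (median 2.4, mean 2.94, adjusted p = 0.029, adjusted p = 0.364 with an estimated correlation). Chemokines had 15 of 17 higher and 1 lower (median 4.21, adjusted p = 1.85e-07, adjusted p = 0.173 with an estimated correlation). Members included Ccl12 at 10.65 and Cxcl14, which had 0 counts in spleen, at least 660-fold higher. The immediate early and heat shock list had 18 of 19 higher and the other not called (median 3.66, adjusted p = 5.24e-09, adjusted p = 0.239 with an estimated correlation). Fosb stood at 613 ± 65.5 against 3.46 CPM. Growth factor and repair genes had 15 of 18 higher and 2 lower (median 3.32, adjusted p = 1.85e-07, adjusted p = 0.122 with an estimated correlation). Vegfa was higher by 5.46 and Mmp14 by 5.59. Complement genes had 11 of 13 higher and the others not called (median 2.62, adjusted p = 1.56e-05, adjusted p = 0.239 with an estimated correlation). C3ar1 was higher by 9.08. Glycolysis had 18 of 19 higher and the other not called (median 1.31, adjusted p = 1.72e-05, adjusted p = 0.302 with an estimated correlation). Lipid handling had 10 of 16 higher and 1 lower (median 1.26, adjusted p = 0.00229, adjusted p = 0.351 with an estimated correlation), and interferon response 19 of 23 higher and 1 lower (median 1.17, adjusted p = 0.000776, adjusted p = 0.484 with an estimated correlation). Members included Oasl2 at 2.34. The inflammatory list had 13 of 19 higher and 3 lower, or 14 and 3 adjusted over the list alone (median 2.21, adjusted p = 0.000159, adjusted p = 0.254 with an estimated correlation). Ptgs2 stood at 7.44 and Il1a at 5.92.

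Oligodendrocyte and endothelial lists were also higher in the brain cells. A second pair of counts is given where those adjusted over the list alone differed from those over all genes. The oligodendrocyte list had 11 of 12 higher and 1 lower (median 6.20, or 6.06 with genes without counts at their bound, camera adjusted p = 0.00222, adjusted p = 0.382 with an estimated correlation). Mobp, a myelin protein, stood at 10.3 ± 4.82 CPM, had 0 counts in spleen and was at least 617-fold higher. The endothelial list had 10 of 12 higher and 1 lower (median 2.47, adjusted p = 0.00607, adjusted p = 0.342 with an estimated correlation). Kdr stood at 23.7 ± 6.30 against 4.17 CPM and Pecam1 was lower by −2.75. The oligodendrocyte and endothelial medians were 4.32 and 2.03 with brain replicates 1 and 2 alone, and 6.95 and 2.73 with 3 and 4 alone. The astrocyte list did not pass (6 of 12 higher and 2 lower, or 7 and 2 adjusted over the list alone; median 1.26; adjusted p = 0.0656), nor did the neuron list (4 of 13 higher and 4 lower; adjusted p = 0.935). The conventional dendritic cell list did not pass by camera (7 of 14 lower and the others not called; median −0.85; adjusted p = 0.0655). By fry it was lower in the brain cells (adjusted p = 0.00176). With brain replicates 1 and 2 alone 11 of 14 were lower and 0 higher (median −1.59). With 3 and 4 alone 6 were lower and 1 higher (median −0.5). Flt3 stood at 258 ± 141 and 208 ± 71.8 CPM (log2 0.31; adjusted p = 0.472) and Cd74 at 10780 and 8540 ± 1483 (log2 0.34; adjusted p = 0.302) in brain and spleen. Both moved with the title style of the brain libraries: Flt3 stood at −0.59 and Cd74 at −0.15 with replicates 1 and 2, not called, and at 0.82 and 0.67 with replicates 3 and 4, where both were called. Cell cycle genes had 12 of 29 lower and 1 higher, or 11 and 1 adjusted over the list alone (median −0.84, adjusted p = 0.0223, adjusted p = 0.784 with an estimated correlation). Mki67 stood at 109 ± 69.5 against 271 ± 83.7 CPM (log2 −1.31, adjusted p = 0.028). The call of Mki67 ended without CD11c brain replicate 3 (−1.10) or 4 (−1.03) and without spleen replicate 2 (−1.17) or 4 (−1.19), and limma-voom did not call it (−0.89, adjusted p = 0.146). It stood at −0.68, not called, with brain replicates 1 and 2 and at −2.49 with 3 and 4, and 3 and 28 of the 29 cell cycle genes were lower.

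Of the 16345 genes, 5097 were higher and 5390 lower in brain than in spleen CD11c cells (64.2%; 2944 and 3286 of them by 2-fold or more), and 48.6% of the calls were higher. With library totals alone the split was 3807 and 7113 (34.9% higher), and the median over all genes moved from −0.036 to −0.302. Upper-quartile scaling moved it to −0.135. All 4 brain libraries lay above all 4 spleen libraries in 4132 genes and below them in 4895.

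Genes were called specific to CD11c cells of the brain when they passed the test with a log2 fold change of at least 1 against each of the other 3 groups, and specific to microglia when both microglia groups passed so against both CD11c groups. There were 435 of the first kind and 699 of the second. With edgeR, 20 simulations in which each gene had the same mean in all groups gave 0. They show only that such counts do not arise without any group difference. They do not gauge how many genes pass because the contrasts overlap. Independent contrasts would give 50.7 and 7.7 genes, but the contrasts share libraries, so these values are no measure of chance either. Lyz2 (lysozyme) stood at 4427 ± 2229 CPM in CD11c cells of the brain against 862, 1382 and 415 in control microglia, ischemic microglia and spleen CD11c cells, but with brain replicates 3 and 4 alone it was 0.87 log2 units above ischemic microglia, under the limit. Tgfbi, a matrix protein, stood at 2391 ± 1414 against 165, 281 and 243, the intermediate filament gene Vim at 1496 ± 418 against 20.3, 190 and 278, and the chemokine receptor Cxcr4 at 1130 ± 263 against 41.9, 147 and 141. Thbs1 and Ifi30 were also among the 8 most abundant, as was Gm42418, a predicted gene whose counts are uncertain. Ifi30 was also under the limit with replicates 3 and 4 alone (0.92 above ischemic microglia). For microglia, Csf1r, the receptor that microglia need to survive, stood at 12960 ± 554 CPM in control and 11230 ± 128 in ischemic microglia against 3950 and 1223 in brain and spleen CD11c cells, and Cst3, Sparc, Serinc3, Fcrls, P2ry12 and Selenop were also among the 8 most abundant. With brain replicates 3 and 4 alone Cst3 (−0.67, not passing) and Serinc3 (−0.96) were under the limit in CD11c cells against ischemic microglia. Of the homeostatic microglia list 19 of 20 members were specific to microglia, and those specific to CD11c cells of the brain included 5 of 16 members of the monocyte list, 4 of 12 of the endothelial list, 5 of 18 of the growth factor list and 4 of 22 of the reactive microglia list. Of the 12 endothelial genes 1 was higher than in ischemic microglia with brain replicates 1 and 2 alone and 8 with replicates 3 and 4 alone.

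**Figure D4:**
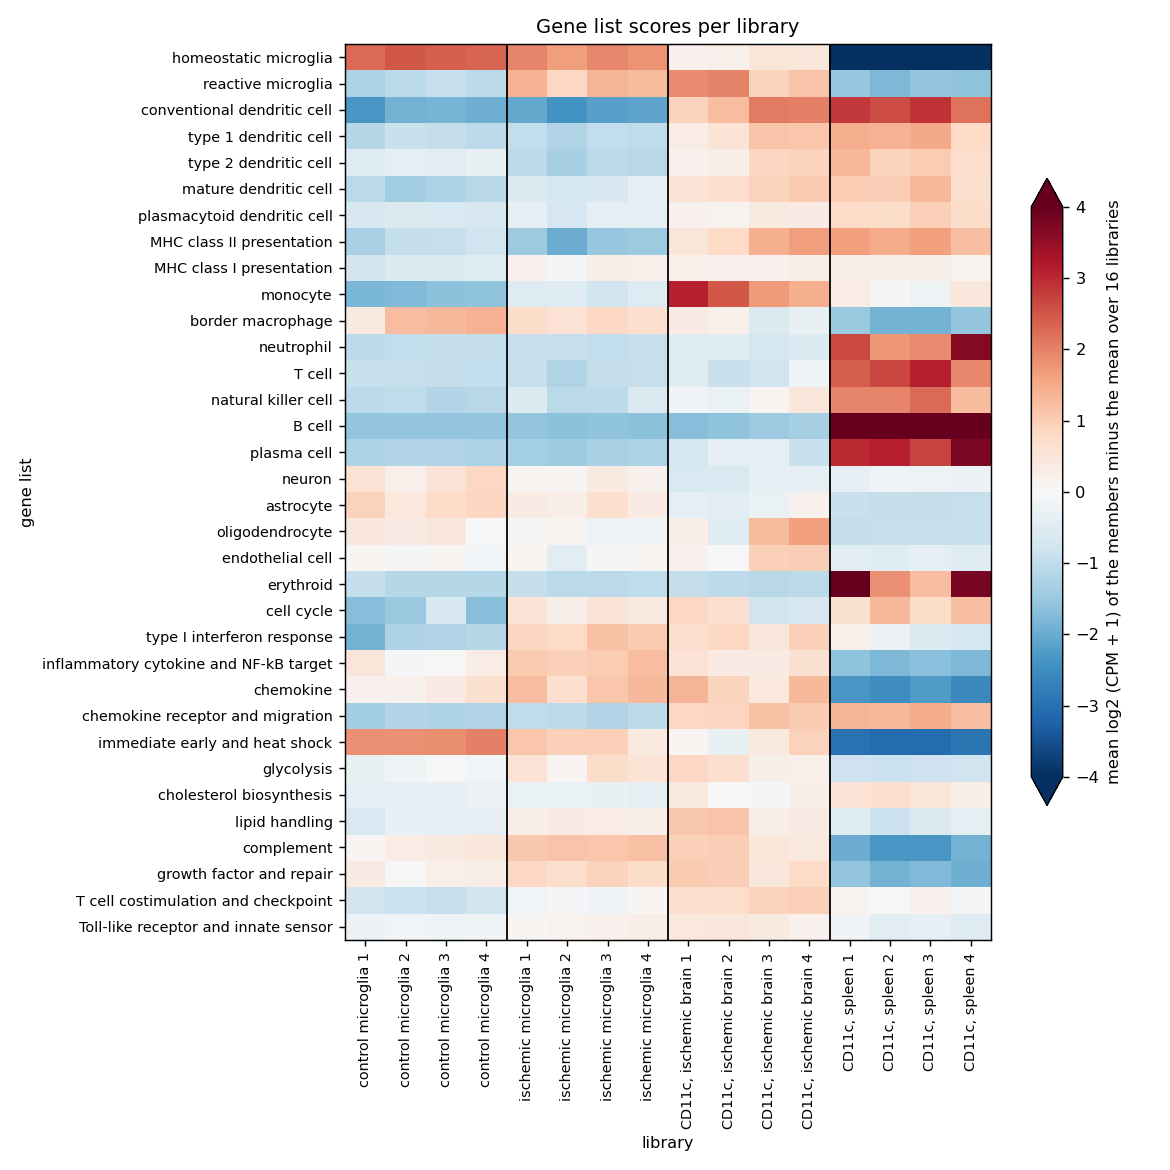
Scores of the 34 gene lists (lines) in the 16 libraries (columns, 4 per group), as the mean log2 (CPM + 1) of the measured members minus the mean of that list over all libraries, with red for higher and blue for lower. The homeostatic microglia score is 10.74 ± 0.09 in control microglia and 3.86 ± 0.08 in spleen CD11c cells before centring (SD, n = 4 each), and the B cell score is 7.82 ± 0.14 in spleen CD11c cells.

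The genes that changed with ischemia in microglia were compared with those that differed between brain and spleen in CD11c cells, 2 comparisons that share no library. The 2889 genes higher in the first and 5097 higher in the second shared 1597 (900.9 for independent lists; odds ratio 3.52, 95% interval 3.23 to 3.82; Fisher's exact test, p = 4.27e-195), and 1533 were lower in both (971.2 for independent lists; odds ratio 2.69, 2.47 to 2.92; p = 2.51e-124). Both comparisons came from a single fit, and the test treats genes as independent of each other. Its p-values and intervals therefore do not measure the spread between libraries. Spp1, Fn1, Gpnmb, Trem1 and Plin2 were higher in both comparisons. Another 436 and 576 genes went opposite ways, and across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.1 and a Spearman correlation of 0.195.

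The 4 CD11c libraries of the brain carried titles of 2 styles, replicates 1 and 2 of one and 3 and 4 of the other, and each pair was also set alone against the other groups. Against ischemic microglia, replicates 1 and 2 gave 3626 genes higher and 3495 lower and replicates 3 and 4 gave 3471 and 3685. Cell cycle genes had 6 of 29 members higher with replicates 1 and 2 and 21 lower with replicates 3 and 4. Oligodendrocyte genes had 1 of 12 higher and 1 lower with the first pair and 9 higher with the second, and endothelial genes 1 and 8 of 12 higher. The conventional dendritic cell and MHC class II lists kept their direction in both pairs, with 12 and 13 of 14 conventional dendritic cell genes and 10 and 12 of 15 MHC class II genes higher. Spp1 stood above spleen by 11.75 log2 units with replicates 1 and 2 and by 8.62 with replicates 3 and 4, Thbs1 by 12.20 and 9.52, and Fn1 by 7.53 and 5.25. Against ischemic microglia, Flt3 stood at 6.19 and 7.65, Kit at 7.19 and 8.54, Dpp4 at 7.16 and 8.25, H2-Aa at 5.34 and 6.40, H2-Eb1 at 5.44 and 6.58, Itgae at 3.86 and 5.16, and Plac8 at 4.44 and 5.82 in the same order. Lyz2 went the other way with 2.20 and 0.87, as did Tgfbi with 3.64 and 2.19 and Thbs1 with 5.49 and 2.86. Cd163 stood at −3.91 and −2.20 and Lyve1 at −4.95 and −3.04. limma-voom gave replicates 3 and 4 low quality weights (0.207 and 0.165). With it Htr7 stood at 9.46, Lyve1 at −4.86, Cd163 at −3.47, Tgfbi at 3.80 and Itgae at 3.78, and the part of the weights in this was not isolated.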

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

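All tests in this part except the correction for GC content and gene length were chosen only after the result was seen, and the rules for reading 2 of them were reworded after their values were known. The test of a few genes taking most of the counts replaced 2 earlier ones on immunoglobulin genes, which lower other genes in spleen and so could not raise the list there. The test of a uniform share replaced one on ratios averaged over the 4 libraries, and its rule was changed again after its values were known. It first argued against a uniform share, but it took the profile of microglia to be the same in all animals, and it is now read as deciding nothing.

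B cell genes were high in the spleen CD11c libraries, with all 14 members of the list higher than in CD11c cells of the brain. A few genes taking most of the counts were argued against, since the 10 most abundant genes took at most 8.44% of the counts of a CD11c library of the brain. This can lower other genes there by at most 0.127 log2 units, and the smallest difference among the 14 members was 3.49. Unselected spleen cells or their free RNA could bring B cell transcripts, but would bring T cell transcripts too. The median of the T cell list was 0.067 of that of the B cell list (18.03 against 269.3 CPM), above the 0.01 that would have argued against this and under the 0.5 that it needs, so it stays open. Reporter expression in B cells or B cells attached to CD11c cells, which a sort without antibodies would not remove, also stays open and was not tested.

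Microglia genes were present in the CD11c libraries of the brain, where 9 homeostatic genes with few counts in spleen stood at a median of 0.336 of their level in ischemic microglia, from 0.228 for Slc2a5 to 0.479 for Trem2. These are means over the 4 libraries, and the order of the genes differed between libraries. Crybb1 ranged from 0.183 to 0.481 and Ltc4s from 0.279 to 0.722. Free RNA of whole brain tissue was argued against, since the most abundant neuron gene reached only 0.007296 of the median of the homeostatic list. RNA of oligodendrocytes alone is not excluded by this, with the oligodendrocyte list at a median of 10.3 CPM and its most abundant gene at 125.8 CPM in these libraries. That gene, Mbp, also stood at 69.4 to 90.4 CPM in the spleen libraries, so its level alone is no sign of oligodendrocyte RNA. A uniform share of the sorted microglia population stays open. With a fixed profile it would move all 9 genes alike between libraries. From replicates 1 and 2 to 3 and 4 they moved by −0.86 log2 units (Fcrls, from 0.498 and 0.451 of the microglia level to 0.264 and 0.260) to 1.24. This range of 2.1, or 1.93 or more without any 1 gene, compares with at most 0.99 between means of 2 ischemic microglia libraries (permutation of libraries within genes, p = 0.00025, at most 0.0015 without any 1 gene). The ratios averaged over the 4 libraries decided nothing (highest over lowest 2.099, permutation p = 0.042, or 0.17 without Trem2). Both permutations treat the 9 genes as independent of each other, although some move together. Their p-values therefore do not measure the spread between the 4 libraries, and no conclusion is drawn from them. Single ischemic microglia libraries also differed unevenly, by a range of up to 1.92 between 2 of them. Replicate 2 had a range of 1.7 against the mean of the other 3, with Fcrls again lowest (−0.92), so microglia whose state varies between animals are not excluded. CD11c-positive microglia, and infiltrating cells that took on microglia genes, stay open and were not tested.

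CD11c libraries 3 and 4 of the brain differed from 1 and 2 in 1679 genes higher and 2213 lower, with 6 of 14 conventional dendritic cell genes higher and none lower (median log2 1.1), and 2 of 16 monocyte genes higher and 7 lower (−1.14). Cell cycle genes had 26 of 29 lower (−1.61). Libraries 3 and 4 held 17932 and 16941 genes with a count against 19379 and 19482, and ribosomal protein genes took 1.31 and 1.72% of counts against 0.989 and 0.934%. GC content or gene length bias was argued against, since the gap between these 2 lists was 2.23 before and 2.22 after correction. Oligodendrocyte and endothelial genes were higher too (medians 2.46 and 1.87). So were 5 of 12 astrocyte, 3 of 13 neuron and 9 of 19 immediate early and heat shock genes, with none lower (medians 0.61, 0.99 and 0.82). Oligodendrocyte and endothelial RNA diluting the rest could not raise the dendritic cell list, which had a median of 1.1. The rule first asked for the monocyte list to rise as well, which left this open because 2 of its genes were higher and 7 lower, and was reworded to ask only for the dendritic cell list. A batch marked by the title style stays open. Distances between the styles were 1.267 times those within them, against 0.876 and 0.914 for the other ways to pair the libraries, but this restates the split already seen and does not favour a batch over a difference between animals, and style and animals cannot be told apart.

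Among 449 groups of 4 values examined, 37 held a library set apart from the other 3, where chance gives about 1 in 20 (22.4). Replicate 2 of ischemic microglia had the highest ribosomal protein share (0.9587%), Saa3 (119.8 CPM) and Tgfbi (519.5 CPM). It had the lowest scores for plasmacytoid dendritic cell (3.412), MHC class II (5.232) and T cell genes (0.683). It was also lowest for Ctsb (10990 CPM), Fcrls (2510), H2-D1 (1390), Itgax (35.23) and Mgl2 (2.073). No biological or technical explanation was tested for this library. Replicate 3 of ischemic microglia had the lowest monocyte (3.759) and chemokine receptor scores (3.719) and the highest astrocyte score (3.115) and Mki67 (153.7 CPM), and replicate 4 the highest Thbs1 (154 CPM).

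Replicate 1 of control microglia had the lowest scores for conventional dendritic cell (1.99), border macrophage (5.687), interferon (3.496) and lipid handling genes (5.771), the highest erythroid score (0.976), and the highest share of haemoglobin genes, at only 7.167e-05% of counts. It was lowest for Ctsd (5864 CPM), Grn (1819), Nlrc5 (15.62) and Plin2 (46.73). Replicate 3 of control microglia was highest for Ccnb2 (7.383 CPM) and Cst7 (12.77) and replicate 4 for the immediate early and heat shock score (9.92). In CD11c cells of the brain, replicate 1 was highest for Adamts1 (132.3 CPM), replicate 3 for Jchain (11.79), and replicate 4 for the mitochondrial share (2.006%) and the MHC class I score (8.262). In spleen CD11c cells, replicate 1 was highest for haemoglobin genes (0.39% of counts) and Lyz2 (535.2 CPM), replicate 2 lowest for Cr2 (240.3), and replicate 3 highest for the plasmacytoid dendritic cell score (5.053).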

How the results depend on the processing

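The fits with either style of brain library titles alone and without immunoglobulin genes, and all regroupings of libraries, were tests chosen only after the result was seen. No paired analysis was possible because the 2 groups of each of the 3 comparisons share fewer than 2 title numbers. Ischemic microglia and spleen CD11c cells, set against each other only for the genes specific to microglia, share 3 title numbers but come from different mouse lines, so these numbers cannot mark shared animals.

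Counts of called genes moved by over 1.5 times with glmTreat, with other minimum fold changes, and in 1 direction with limma-voom. With glmTreat against a log2 fold change of 1, CD11c cells against microglia gave 1036 genes higher and 371 lower, ischemic against control microglia 396 and 97, and brain against spleen CD11c cells 2167 and 2263. With limma-voom 4961 genes were lower in ischemic microglia, against 2945, and 4107 higher, against 2889. A minimum log2 fold change of 2 left 179 genes specific to CD11c cells of the ischemic brain and 154 genes specific to microglia, and no minimum gave 1080 and 1690, against 435 and 699. Asking for a log2 fold change of at least 1 in each of the 2 comparisons, 491 genes were higher and 409 lower in both, where independent lists would share 221.7 and 179.7.

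DESeq2 called 3401 genes higher and 3674 lower in CD11c cells than in microglia, 3225 and 3259 with ischemia in microglia, and 5564 and 5992 between brain and spleen. In each scaling, filter and test tried on all 16 libraries, no gene called in both fits changed direction. Leaving out 1 library at a time gave 2812 to 3289 genes higher and 2526 to 3341 lower in CD11c cells than in microglia, 2297 to 2693 and 2314 to 2881 with ischemia, and 4829 to 5217 and 5048 to 5703 between brain and spleen. Without the 2 CD11c libraries titled with the number 11, brain against spleen gave 4669 and 5222, and without immunoglobulin genes 5069 and 5219.

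Of 5818 values of named genes in other settings 5655 kept their call or lack of it, 160 lost the call, 2 gained it and 1 turned direction. S100a9, called higher in CD11c cells than in microglia (log2 3.01, adjusted p = 0.0316) at under 2 CPM in every library of both groups, had a log2 of −0.065 with limma-voom. It stood at 0.45 with CD11c brain replicates 1 and 2 alone, where the call ended, and at 3.90 with replicates 3 and 4 alone. Its call also ended without brain replicate 3 (2.55) or 4 (2.53) and without ischemic microglia replicate 2 (2.80), 3 (2.71) or 4 (3.09). Gene list calls depended on the correlation between genes. With an estimated correlation camera called 2 lists in CD11c cells against microglia, 0 in ischemic against control microglia and 2 between brain and spleen. The preset correlation called 14, 16 and 21. Each list had a single estimate over all 16 libraries, such as 0.867 for cell cycle and 0.66 for interferon genes. For the microglia comparison it therefore includes the spread among CD11c libraries of the brain. Between their title styles 26 of 29 cell cycle genes differed. The 0 in ischemic against control microglia is beside 5 lists at an unadjusted p under 0.05 with camera and 18 lists called by fry. Fry called 20 lists in CD11c cells against microglia and 27 between brain and spleen. Leaving out members of other lists ended the call of the monocyte list between brain and spleen (adjusted p = 0.0998) and added the endothelial list in CD11c cells against microglia (0.0385) and costimulation between brain and spleen (0.0312).

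The counts of genes were set against the other ways to part the same libraries. Each other way mixes the 2 groups, so a group difference widens the spread within its parts and few genes are called. The lowest share that can be reached is 1 of 35. The result argues only against libraries that are alike in both groups. For CD11c cells against microglia the real split alone of 35 (1) gave as many genes in either direction, with 43 genes as the highest of the others, against 3213 and 3130. For ischemic against control microglia it was again 1 of 35 with 0 genes as the highest other in edgeR, and for brain against spleen 1 of 35 with 6. The 435 and 699 specific genes were reached by 1 of 100 regroupings of all 16 libraries, which was the real grouping itself. The highest other counts were 1 and 0, which excludes only that the libraries are alike across all groups. Other regroupings that kept microglia apart from CD11c libraries gave at most 0 genes specific to CD11c cells of the brain with edgeR. However, 17 of 100, the real grouping included, gave as many genes specific to microglia (highest other 731). That count therefore rests on the difference between the populations. The shared 1597 and 1533 genes were also reached by 1 of 100 regroupings, again the real grouping, with 0 as the highest other. This decides nothing about the sharing, since other splits of the microglia libraries called 0 genes with edgeR and could share none. Chance was not excluded for the number of lists called. As many were called by 9 of 35 splits in the first comparison (14, highest other 18), 9 of 35 in the second (16, highest other 18) and 2 of 35 in the third (21, highest other 22). Most of the other splits that called as many mixed the groups unevenly and kept part of the real difference. The test therefore could not exclude chance and does not show that the list calls arose by it.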

Other observations

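The tests cited here were, apart from the gene list tests, leaving out single libraries and other minimum fold changes, chosen only after the result was seen. Some genes abundant in CD11c cells of the brain had lower means in each of the other 3 groups. Il1r2, a decoy receptor for interleukin 1, stood at 571 ± 226 CPM against 1.94 in control microglia, 4.40 in ischemic microglia and 7.67 in spleen CD11c cells (SD, n = 4). Cytip, a regulator of cell adhesion, stood at 783 ± 167 CPM against 9.20, 11.0 and 327. Dab2, an endocytic adaptor, and Fosl2, an AP-1 transcription factor, stood at 659 ± 249 and 717 ± 124 CPM in CD11c cells of the brain. In control microglia, ischemic microglia and spleen Dab2 stood at 257, 295 and 3.06 CPM and Fosl2 at 153, 216 and 14.5 CPM. Cst7, a cystatin of reactive microglia, rose with ischemia in microglia by 4.29 log2 units and was higher in brain than in spleen CD11c cells by 4.47.

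The CD11c libraries of the brain combined dendritic cell and antigen presentation genes (Flt3, Cd74) with monocyte and macrophage genes (Ccr2, Thbs1, Spp1) and a part of the microglia program (Fcrls, Trem2). These data are consistent with a mixture of cell types among sorted CD11c cells, and the shift between the 2 title styles may reflect varying shares of them. In that shift 6 of 14 conventional (median log2 1.1), 4 of 16 type 1 (0.75), 3 of 15 type 2 (0.87) and 1 of 20 mature dendritic cell genes (0.41) and 7 of 15 class II genes (1.05) were higher, and none of these lists had a gene lower. Of the monocyte genes 7 of 16 were lower and 2 higher (−1.14), and of the border macrophage genes 6 of 12 were lower and 2 higher (−1.11). Cell cycle genes were lower (26 of 29) and fewer genes had a count in replicates 3 and 4, so a difference between batches stays open as well. A share of CD11c-positive microglia is a candidate explanation for the third part. The range of 2.1 log2 units in the shifts of 9 homeostatic genes between the title styles leaves open whether these are microglia like the sorted ones. Sequencing of single cells sorted in the same way would tell a mixture from cells that express these genes together.

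The interferon, cell cycle and class I lists rose in ischemic microglia with the preset correlation of camera. They did not pass with a correlation estimated over all 16 libraries, CD11c cells included (adjusted p = 0.18, 0.418 and 0.18). Cd74 and H2-Aa fell, but the class II list did not pass (adjusted p = 0.0904). The fall of Cd74, H2-Aa, Cd209a and Mgl2 could come from fewer border macrophages or dendritic cells among the CX3CR1-positive cells rather than from microglia, and the border macrophage list itself did not pass the test. Leaving out any 1 library left Cd74 between −1.70 and −1.33 and Mgl2 between −2.59 and −2.10, so no single library made these falls. The fall of Hspa1b, Hspa1a and Jun might be a difference in the handling of control and ischemic tissue, since whole brain and a single hemisphere were dissociated. Hspa1b stayed between −4.07 and −3.52 when any 1 library was left out, and no test of handling was possible with these labels.

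Genes higher with ischemia in microglia and higher in brain than in spleen CD11c cells, such as Spp1, Fn1, Gpnmb and Plin2, may mark a response to injured tissue shared by both populations. With a log2 fold change of at least 1 in each, 491 genes were higher in both, against 221.7 for independent lists. CD11c cells of the brain and spleen also differ in tissue without injury, and a control brain CD11c group, which would part these, was not analysed here. Microglia among the sorted CD11c cells of the brain, which stay open above, would also raise such genes over spleen. Homeostatic genes stood there at a median of 0.336 of their level in ischemic microglia. The shared genes therefore need not come from 2 separate populations. Spp1, Thbs1 and Gpnmb differed between the libraries of the 2 title styles, so their size in CD11c cells is less certain than their direction.

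The B cell genes in spleen CD11c libraries could affect other fold changes between brain and spleen. Leaving out immunoglobulin genes gave 5069 genes higher and 5219 lower against 5097 and 5390, and the share of other B lineage transcripts in single genes was not estimated. Cells or RNA of the B lineage in the sorted fraction are a candidate source. The ratio of 0.067 between the T cell and B cell lists leaves open whether unselected spleen cells brought them. Sequencing of single spleen cells sorted in the same way would settle whether these genes belong to CD11c-positive cells.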
